A study of Mus musculus with 10 samples.

How the data were processed

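The DNase samples came from 3T3-L1 nuclei harvested 4 h after induction, per the labels. Nuclei were treated with DNase I, short fragments were separated on a sucrose gradient and the fragments were sequenced. Per the labels, both DNase samples are further sequencing of 1 earlier library, and the authors combined them with the earlier reads before calling DHS sites and footprints. The lists are thus pooled calls from 1 library, and no comparison between replicates could be made. The genome build is mm9, and HOMER is named for the DNase samples and Bowtie, HOMER and DESeq for the RNA samples, per the submitters' processing notes. The versions and the step each tool performed are not given in the sources used here. The footprint caller is not given in the sources used here.

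Both deposited lists were used. The DHS list gives chromosome, start and end of each site and no value of strength, so site width was the only measure of site size. The footprint list gives chromosome, start, end and a p-value column per the file headers. That deposited column was treated as a score, because all its values are negative, the highest being -3.54, and 496 are -Inf, and neither its scale nor its log base is given in the sources used here. The deposited score was used only to rank footprints within the list. The names of the deposited lists carry a false discovery rate of 0.01 and a maximum width of 30 bp for footprints, and a false discovery rate of 0 for DHS sites. The largest footprint width was indeed 30 bp. These limits set which footprints could be seen, and the 38035 footprints at exactly 30 bp (11.6%) could be parts of longer protected stretches. A deeper library allows more footprints to be called, in particular in sites with many cuts, and no read depth accompanies the lists. Differences in footprint number between sites can therefore reflect the number of cuts as well as protein occupancy. Positions are printed 1-based, with starts raised by 1 from the BED form, which was assumed for both lists.

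A footprint was assigned to a site at an overlap of at least 1 bp, and both counts of overlap were checked with bedtools. Sites were split into 5 groups of equal number by width, and density was the number of footprints per kb of site sequence. The chromosome was the unit of the sign-flip permutation tests (20 chromosomes, 100000 resamples, two-sided). For gaps, the footprints of each site were placed again 1000 times at random in the same site without overlap, and the share of gaps under 10 bp was compared, two-sided. For clusters, sites 12500 bp or less apart were joined. Expected numbers of footprints were taken from the mean number per site in 50 classes of site width. Draws of footprints in proportion to site width, set beside the correlation with width, were added after the data were seen. Chromosome X was compared with the 19 autosomes by its rank, with an exact two-sided p. The 95% interval of a share is Wilson's. Per Mb values use 1 Mb bins or the distance from the first to the last site of a chromosome, since chromosome lengths of mm9 were not used here.

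The regions named in the report follow a rule fixed before the data were examined, as were its main tests. Settings and closing tests added later are named as such. The rule takes the 10 DHS sites with the most footprints, the 5 clusters with the most footprints and the 5 footprints with the strongest finite score. Any other region named was chosen after its values were seen. The planned search for 23 motifs in footprints, the comparison of sites near 12 gene lists (markers of other cell types included) and the knockdown comparison were not run. The first of these needs the mm9 sequence and the second its gene annotation, and neither was used here. Gene positions at hand were on GRCm38, so no gene name was attached to a region. Expression values of the 8 RNA samples were not analysed here.

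The steps were tested on 4 simulations of 16000 sites each. Uniform placement gave a gap ratio of 1.01 (permutation p = 0.886), footprints placed in close pairs gave 7.61, footprints drawn toward the centre gave a difference in relative distance of -0.175, and sites made denser when wide gave a density difference of 7.31 per kb. Drawing footprints toward the centre alone raised the gap ratio to 1.48, so placement within the span of a site's footprints was added as an alternative after the data were seen, with gaps of 0 bp allowed and with footprints at least 1 bp apart, the smallest gap in the list. In the second form every placement was equally likely. Other alternatives were the stronger 50% of footprints, the wider 50% of sites, stricter overlap, merging of touching footprints or of those 2 bp or less apart, autosomes alone, gaps under 20 bp, joining at 5000 and 20000 bp, and leaving out bins with 5 or more footprints at -Inf. The stronger 50% was taken among finite scores, so the 496 footprints at -Inf were left out of it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.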

Results

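The data describe accessible chromatin in 3T3-L1 cells, a mouse fibroblast line committed to become fat cells, 4 h after the start of adipogenic differentiation. The cells had received dexamethasone (a glucocorticoid, 1 µM), 3-isobutyl-1-methylxanthine (a phosphodiesterase inhibitor that raises cyclic AMP, 0.5 mM), insulin (1 µg/mL) and 10% fetal calf serum. DNase I cuts open chromatin, so stretches with many cuts mark DNase I hypersensitive (DHS) sites, and short stretches inside them with few cuts, called footprints, mark DNA protected by bound protein. The DNase group had 2 samples, a single-end and a paired-end run of 1 library, which the authors pooled with an earlier run of that library. The site list and the footprint list therefore describe 1 library with no replicates. The p-values below describe these lists and carry no information on variation between cultures. No read counts accompany either list, so the depth behind each site or footprint is unknown. The study also holds 8 RNA-seq samples in 4 groups of 2, cells carrying a scrambled shRNA or an shRNA against C/EBPβ (a transcription factor that acts early in adipogenesis), each at 0 h and at 4 h. Expression in these groups was not analysed here.

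The first question was how much of the open chromatin carried protein footprints at 4 h. The authors called 129028 DHS sites with a median width of 532 bp (interquartile range 380 to 719 bp), which together covered 80.7 Mb of the mm9 genome. They called 329076 footprints of 8 to 30 bp, with a median of 21 bp. All 329076 footprints (100%) lay fully inside a DHS site and covered 8.19% of the DHS sequence. The 100% would follow if footprints were searched for only inside sites, so it is not a result about binding. A footprint was present in 58632 sites, 45.4% of the total (95% Wilson interval 45.2 to 45.7%, which covers counting error only and treats sites as independent). The other 70396 sites (54.6%) held none in the footprint list as used here, and whether that list leaves out regions is not known. With the stronger 50% of footprints alone, the share of sites with a footprint was 27.8%, and among the wider 50% of sites it was 75.2%.

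Footprints were concentrated in a minority of sites. The mean was 2.55 ± 5.05 footprints per site (SD over 129028 sites), and sites with any footprint held a median of 4. A single footprint was found in 13841 sites (10.7%), 2 to 4 in 19864 sites (15.4%) and 5 to 9 in 14759 sites (11.4%). The 10168 sites with 10 or more footprints were 7.88% of all sites and held 161576 footprints, 49.1% of the total. Their median width was 1304.5 bp, against 419 bp for sites without a footprint and 715 bp for all sites with at least 1. There were 1932 sites (1.5%) with 20 or more footprints and 78 sites with 50 or more.

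Wide sites held more footprints than narrow ones, both in number and per length of DNA. Density rose from 0.350 footprints per kb in the narrowest quintile of sites (251 to 340 bp) through 0.643, 1.62 and 3.90 to 7.28 per kb in the widest (793 to 13152 bp). Density was taken over the whole width of a site, although few footprints lay near site edges, and no correction was made for this. The median finite score went from -3.87 in the narrowest quintile to -4.56 in the widest, where the highest score in the list was -3.54. The median width of these footprints fell from 27 to 19 bp. Read depth is unknown, so denser binding in wide sites cannot be told apart from footprints being easier to call there. The share of sites with a footprint rose from 7.23% in the narrowest quintile to 91.5% in the widest, which held 69.7% of all footprints. With the chromosome as the unit, the widest quintile exceeded the narrowest by 6.84 ± 0.747 footprints per kb (SD, n = 20 chromosomes), and did so on 20 of 20 chromosomes. The two-sided sign-flip permutation test gave p = 1e-05, the smallest that 100000 resamples allow. With the stronger 50% of footprints alone the difference was 3.95 per kb, a setting that favours wide sites, whose footprints had stronger scores. Across sites, the number of footprints correlated with width at a Spearman rho of 0.72 and a Pearson r of 0.80, each with a permutation p of 0.001, the smallest that 1000 permutations allow. A wider site holds more footprints even at a constant density, so that p was bound to be small. With the same number of footprints drawn in proportion to site width 1000 times, rho was 0.575 on average and at most 0.580, and r was 0.718 on average and at most 0.724, below the observed values. Within single chromosomes rho ran from 0.61 to 0.79 and r from 0.75 to 0.87. Adjusted by Benjamini-Hochberg over the 6 correlations across sites that were computed, those between neighbouring sites included, both p-values were 0.0012. Sites are not independent replicates.

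**Figure D1:**
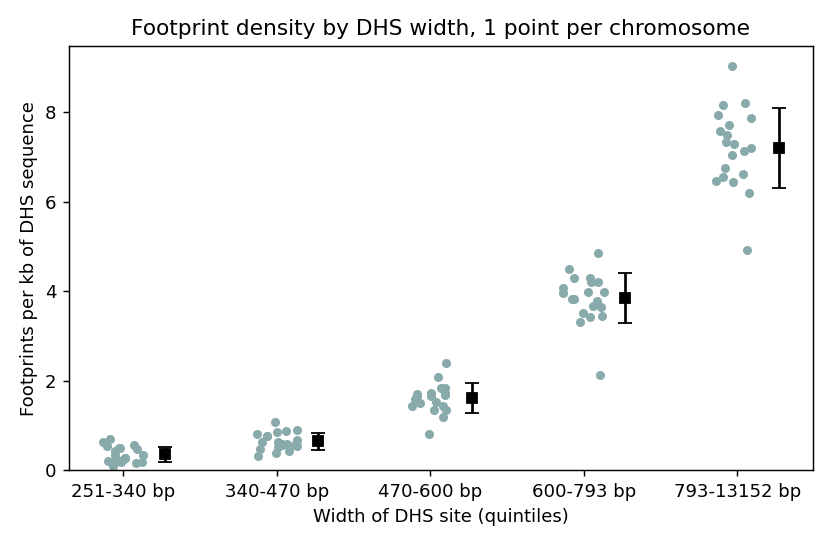
Footprints per kb of DHS sequence (y axis) in 5 equal groups of sites by width in bp (x axis), with 1 point per chromosome for the 19 autosomes and X, and the mean and SD over chromosomes as a square with bars. Mean density rises from 0.356 ± 0.174 per kb in the narrowest sites to 7.20 ± 0.891 per kb in the widest.

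Within a site, footprints lay toward the middle. The mean distance of a footprint's centre from the site's centre was 0.292 of the distance from centre to edge, against 0.489 for uniform placement. The difference was -0.197 ± 0.00995 (SD, n = 20 chromosomes) and had this sign on 20 of 20 chromosomes (two-sided sign-flip permutation test, p = 1e-05, the smallest possible). In all, 83.1% of footprints had their centre nearer to the site's centre than to its edge. Only 0.119% had it in the outermost part, from 0.9 to 1 of the distance from centre to edge. How cuts fall along a site is unknown here, and uniform placement takes no account of it. The test thus cannot separate where protein binds from where footprints could be called.

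Footprints of one site also lay close to each other. Among 270444 gaps between neighbouring footprints in the 44791 sites with 2 or more, 24.4% were under 10 bp, against 11.04% when the same footprints were placed at random in their own sites without overlap. The ratio was 2.21 (two-sided permutation test by random placement, p = 0.002, the smallest that 1000 placements allow), and the median gap was 20 bp against 58.1 bp. Most of this excess was absent when placement was limited to the span from a site's first to its last footprint. The smallest gap in the list was 1 bp, and with random placement kept at least 1 bp apart in the 36236 sites with 3 or more footprints, 24.9% of 261889 gaps were under 10 bp against 24.4% at random, a ratio of 1.02 (the same kind of permutation test, p = 0.002). The ratio was 0.989 where random gaps of 0 bp were allowed, a length that no observed gap had. Against the placement at least 1 bp apart, gaps of 5 to 20 bp were 1.17 times as frequent as random, gaps of 1 to 2 bp 1.15 times, gaps of 3 to 4 bp 0.877 times and gaps of 21 to 59 bp 0.942 times.

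**Figure D2:**
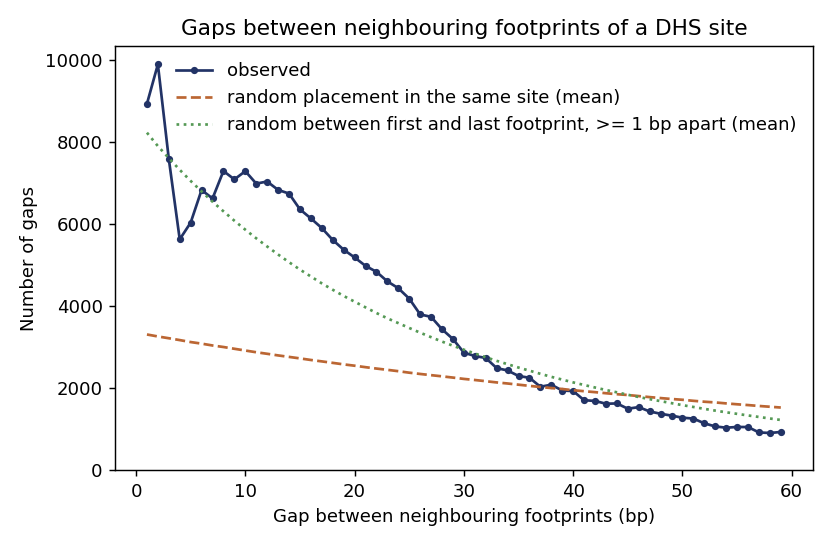
Number of gaps (y axis) by gap length in bp (x axis) between neighbouring footprints of a DHS site, as observed (points and line), with random placement over the whole site (dashed) and with random placement at least 1 bp apart between the first and the last footprint of sites with 3 or more (dotted). The observed median gap is 20 bp, against 58.1 bp for placement over the whole site and 24 bp for placement within the span.

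The sites with the most footprints were few, broad and spread over 6 chromosomes. A site of 13152 bp on chromosome 19, from 5836635 to 5849786, held 259 footprints, or 19.7 per kb, the most of any site. Next came a site of 6179 bp on chromosome 17, from 39979772 to 39985950, with 172 footprints. A pair of sites on chromosome 10 followed, from 116717300 to 116728628 with 151 footprints and from 118047704 to 118058030 with 147. A site of 4981 bp on chromosome 1, from 24618210 to 24623190, held 144 footprints and was, with 28.9 per kb, the densest of the 10 sites named by the fixed rule. The remaining 5 held 104 to 143 footprints. They lay on chromosome 5 from 33075852 to 33085400 and from 143578923 to 143585809, on chromosome X from 166432132 to 166441397, and on chromosome 17 from 3078779 to 3085033 and from 26638318 to 26646966. Together the 10 sites held 1455 footprints, 0.442% of the total. With the stronger 50% of footprints alone, the number fell by more than 1.5 times in 4 of the 10 sites, to between 51 and 95. Genes at these positions were not analysed here.

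Of the 5 footprints with the most extreme finite scores, 2 lay in a single broad site on chromosome 17. The score, the authors' own value per footprint, is negative throughout, and its scale is not given in the sources used here. More negative values were read as stronger. The strongest finite value, -107.7, belonged to a footprint on chromosome 4 from 79648780 to 79648800, in a site of 3195 bp with 80 footprints. The second (-105.9, from 39983670 to 39983696) and the fifth (-94.1, from 39984925 to 39984953) both lay in the chromosome 17 site with 172 footprints. The third (-105.6) was on chromosome 6 from 3150814 to 3150840, and the fourth (-96.8) on chromosome 12 from 98299837 to 98299865, in a site of 723 bp with 11 footprints. The median of all finite scores was -4.38. It was -31.5 among the 172 footprints of the chromosome 17 site and -24.0 among the 144 of the chromosome 1 site, whereas the other 8 of the 10 sites had medians between -6.25 and -4.37. Footprints covered 46.1% of the chromosome 17 site and 48.6% of the chromosome 1 site, against 23.9 to 33.1% of the other 8. With the stronger 50% of footprints alone, both kept all of theirs (172 and 144), whereas each of the other 8 lost some. No read counts accompany the lists, so whether the chromosome 17 and chromosome 1 sites had more cuts was not tested. Whether they are open chromatin like the other 8 was not tested either. Their scores therefore need not mark stronger protection.

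Sites with many close neighbours were also described as groups. Joining sites 12.5 kb or less apart gave 57598 groups, of which 28398 were single sites and 5409 held 5 or more. These 5409 clusters contained 38658 sites (30.0%) and 119801 footprints (36.4%). Sites in them held 3.10 footprints on average, against 2.32 for the rest, but they were also wider (median 577 against 513 bp), and their widths alone predicted 3.00 against 2.36. The number of such clusters was set by the joining distance and was 1643 at 5000 bp and 8436 at 20000 bp. The median distance between neighbouring sites was 10269 bp, below the joining distance of 12.5 kb, so most neighbouring pairs were joined. The numbers are a description, and were not compared with a random arrangement of sites.

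The cluster with the most footprints was on chromosome 10 from 116813773 to 117230303. It had 172 sites and 2300 footprints in 416.5 kb, and 100% of its sites held a footprint. The second, on chromosome 11 from 3023242 to 3099924, packed 886 footprints into 44 sites over 76.7 kb, and the third, on chromosome 2 from 77707577 to 77865404, had 769 footprints in 72 sites. In both, 100% of sites held a footprint. The fourth, on chromosome 19 from 5771084 to 5850696, included the site with 259 footprints and had 531 in 21 sites. The fifth, on chromosome 10 from 106642299 to 106694125, had 380 in 24 sites. Among the 87 clusters of 20 or more sites, the median share of sites with a footprint was 54.5%, and it was 100% in 6. Relative to the number predicted from the widths of their sites, these 5 clusters, chosen for their footprints, held 3.09, 2.67, 2.30, 3.44 and 1.5 times as many, in the order given.

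**Figure D3:**
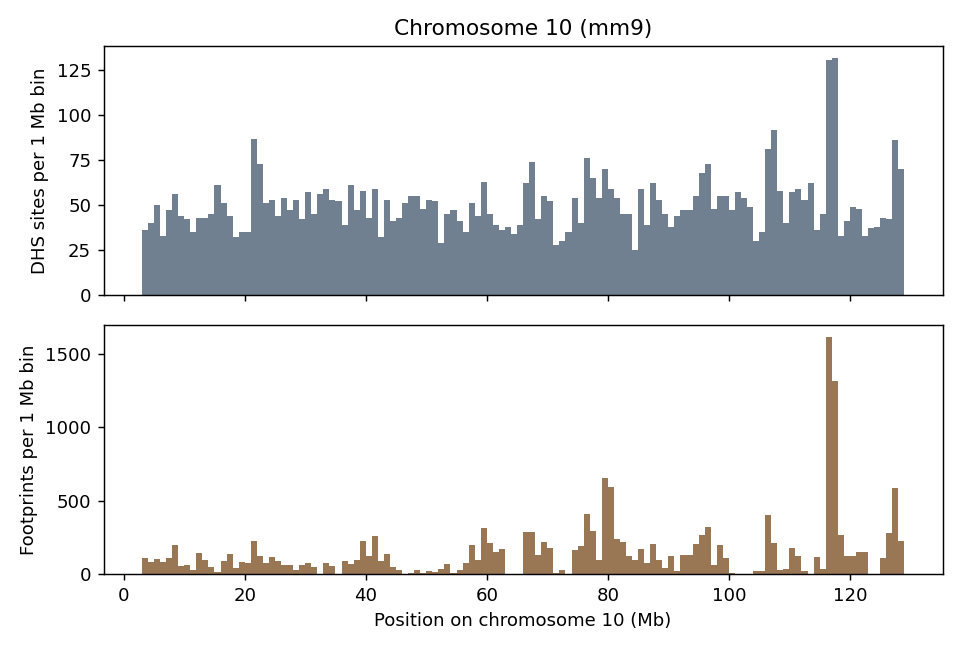
DHS sites (upper panel) and footprints (lower panel) per 1 Mb bin along chromosome 10, by mm9 position in Mb (x axis). The bins that start at 116000001 and 117000001 hold 1613 and 1316 footprints, against a median of 92 per bin over the genome.

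Chromosomes differed in how many sites they carried and how many footprints each site held. Over the 19 autosomes there were 51.7 ± 6.33 sites per Mb (SD, n = 19), counted between the first and last site of each chromosome. Chromosome 6 had the most, 69.3 per Mb, followed by chromosome 19 with 61.8. Footprints per site ran from 1.90 on chromosome 14 to 3.78 on chromosome 11, with a mean of 2.62 ± 0.515. Chromosome X was the lowest of the 20 on each measure. It had 30.9 sites per Mb, 0.621 of the autosomal median of 49.8. A site on X held 1.36 footprints on average, 28.7% of its sites had a footprint, and its sites carried 2.33 footprints per kb against an autosomal median of 4.16. Sites on X were also narrower, with a median width of 478 bp against an autosomal median of 534 bp. Its footprints were 0.629 times the number predicted from width, against an autosomal median of 0.998. Read depth over X is unknown, so fewer cuts there were not tested. The exact two-sided rank p was 0.1, the smallest that 1 chromosome among 20 allows, so the design cannot pass a threshold of 0.05. Chromosome Y had 3 sites and 1 footprint.

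**Figure D4:**
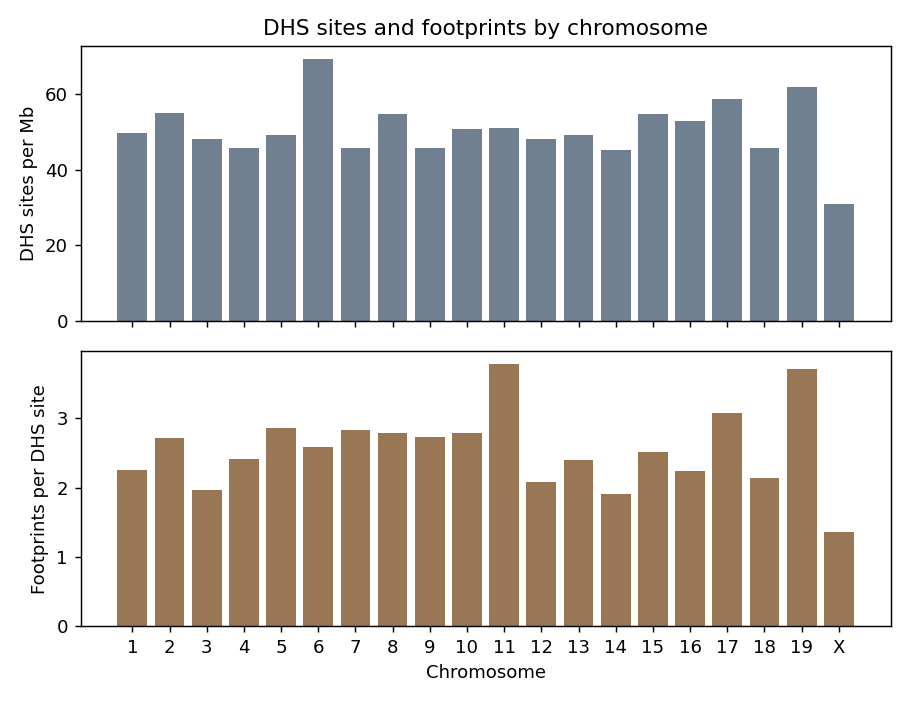
DHS sites per Mb (upper panel) and mean footprints per DHS site (lower panel) for each autosome and X, with 1 bar per chromosome from 1 library, so there are no error bars. Chromosome 6 is highest in sites per Mb (69.3), chromosome 11 in footprints per site (3.78), and X is lowest in both (30.9 and 1.36).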

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

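A signal outside the comparisons of the report was the set of 496 footprints whose score is -Inf (0.151% of the list), which were counted as footprints but have no usable value. Finite scores reach -107.7, and no cause was tested. Compared with the typical footprint, these lay in narrower sites (median width 711 bp, against 1027 bp over all footprints) that held fewer footprints (median 2 against 9), and 25.2% of them had the maximum width of 30 bp. The 1 Mb bin of chromosome 17 from 13 Mb held 20 of them, against 0.647 for an even share of its 429 footprints. That bin also had the most DHS sites of any, 205, and held 0.441 times the footprints predicted from site width. Bins with 5 or more such footprints numbered 15 and together held 120.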

How the results depend on the processing

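No paired analysis was possible because both lists are the authors' pooled calls from 1 library, and the RNA groups, whose labels share experiment numbers, were not analysed here. The in-span placements, merging at 2 bp, removal of bins rich in -Inf scores, and the stronger 50% and wider 50% settings for chromosome X were chosen after the data were seen. Of the comparisons' values under alternatives, 48 kept their direction and their side of the threshold (or, without a test, their range), 7 moved and 1 reversed. Of the 48, at least 19 say nothing about stability. They are the 5 for chromosome X, whose p of 0.1 cannot pass a threshold, and values that the setting left exactly equal, such as the number of clusters when only footprints change, or the share of footprints in sites, which is 100% with every footprint fully inside a site. Taking the stronger 50% of footprints moved the share of sites with a footprint to 27.8%, and the density difference fell from 6.84 to 3.95 per kb, as fewer footprints remain. Taking the wider 50% of sites moved the share of sites with a footprint to 75.2%, the share of footprints in sites to 94.7% and the number of clusters to 1706, since narrow sites were removed. Autosomes alone gave 46.1%, outside the counting interval. Joining at 5000 bp gave 1643 clusters and at 20000 bp 8436. The reversed value was the ratio of short gaps, 0.989 with placement inside the span of a site's footprints. It rested on 5002 random gaps of 0 bp, where 0 were observed. With footprints at least 1 bp apart the ratio was 1.02, or 1.04 under a simpler draw, and under the settings that used whole sites it ran from 1.81 to 2.73. Under the other settings the density difference lay between 5.91 and 6.96 per kb. The 5.91 came from the wider 50% of sites, where quintiles were formed again within that subset, so it compares other widths. The correlation with width lay between 0.63 and 0.73. Its p-values were bound to be small even at a constant density, so they say nothing about stability either. The difference in relative distance lay between -0.218 and -0.196, past its threshold. Stricter overlap changed nothing, since every footprint lay fully inside a site, and merging of touching footprints changed nothing, since none touch. Of the named sites' values, 16 stayed within 1.5 times and 4 moved. The motif, gene-list and knockdown alternatives were not run. Unknown read depth limits every count of footprints.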

Other observations

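The test of dense stretches on chromosome 6 and the check for very broad sites on chromosome 10 were chosen after the results were seen. So were the tests of random placement for close pairs and of chance order for runs without a footprint. The shuffles of 30 bp footprints within sites were also chosen then. The other 4 tests were set before they were run, but were not among the main tests fixed before the data were examined. The patterns on chromosomes 6 and 10 were themselves picked from the results.

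In the lists as used here, long stretches of the genome had DHS sites but no footprint. Whether the footprint list leaves out regions is not known, and runs without a footprint would also follow from that. On chromosome 15 from 45707876 to 48364646, 179 sites in a row held none, where their widths predicted 158. The next longest runs were 176 sites on chromosome 12 from 62182194 to 65091635, 151 sites on chromosome 14 from 90309146 to 93119881, 146 sites on chromosome 8 from 64454536 to 66474080 and 145 sites on chromosome 1 from 142685000 to 144925897. In total, 632 runs of 20 or more sites held 26110 sites (20.2% of all) over 527.0 Mb, where widths predicted 16666 footprints. Footprint numbers shuffled among sites of the same chromosome and width class left 338.1 sites in such runs on average and at most 522. The longest run in 100 shuffles was 69 sites, against 179 observed, so chance order of sites of the same width is argued against.

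Neighbouring sites likewise held like numbers of footprints. For 43097 pairs of sites less than 5 kb apart the rank correlation was 0.43. After removal of the part predicted from width it was 0.201, above the highest of 1000 permutations within chromosomes (0.0243), so like widths of neighbours are argued against as the whole of the relation. It was 0.170 for sites 5 to 20 kb apart and 0.118 at 20 to 100 kb (permutation p = 0.001 for all 3 classes, the smallest possible, adjusted p = 0.0012 over 6 correlations) and 0.00946 beyond (p = 0.708). The hypothesis that footprints follow regional domains may account for both patterns. Weaker sites with fewer cuts in some regions, or regions left out of the footprint list, would give the same picture. None of these explanations, regional domains included, was tested.

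The neighbouring 1 Mb bins with the most footprints were those of chromosome 10 from 116000001 to 118000000, with 2929 footprints in 263 sites. Of its sites below the genome's median width, 81.3% held a footprint, against 15.7% of such sites over the genome. Picking the stretch for its footprints raises that share. The 2 richest sites held 231 of the 2929 footprints, so a pair of very broad sites does not account for most of them. Without those 2 sites the poorer of the 2 bins still held 1236, against a 99th percentile of 571 over all bins. Site counts already seen fixed this outcome, so it is a description and not a test. More reads over the stretch, for example from extra copies of it in the cell line, could not be tested without read counts. Footprints there were 2.67 times the number predicted from width, against a median of 0.903 over 2435 pairs of neighbouring bins, but the stretch was picked for its footprints, so this ratio does not decide, and no biological explanation was tested.

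Chromosome 6 had the most sites per Mb. A few dense stretches are argued against as the whole of it, since its median of 67 sites per 1 Mb bin exceeded that of the next autosome, 61 on chromosome 19, by 6 (bootstrap interval 1 to 13). Chromosome 6 was picked for its number of sites, so this interval may lie too high. More reads along the chromosome cannot be told apart from other causes, because the ratio of footprints to the number predicted from width was 1.11, rank 4 among the 19 autosomes, with a median of 0.998 and a maximum of 1.26. An extra copy of the chromosome in this line could also add sites and was not tested.

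Gaps of 1 to 2 bp numbered 18830, against 13222 of 3 to 4 bp. Pairs 1 to 2 bp apart included a footprint of the maximum width of 30 bp in 21.3% of cases, against 11.3% of pairs 5 to 20 bp apart, a ratio of 1.89 (1.68 to 2.24 over chromosomes). The reference was the low one, since the share was 17.7% over all pairs and 26.7% at 60 bp or more. With the 30 bp footprints shuffled within their sites 200 times it was 19.6% on average, and at most 20.2%, for pairs 1 to 2 bp apart. For pairs 5 to 20 bp apart it was 16.1% on average, and at least 15.9%. The observed share at 1 to 2 bp was thus above all 200 shuffles, at 1.09 times their mean. At 60 bp or more it was 1.16 times the shuffled mean, so an excess is not particular to close pairs. It stays open whether longer protected stretches were split at the width limit. Uniform random placement within the span gives most of these pairs, and is argued against only for the excess. In sites with 3 or more footprints 18623 were 1 to 2 bp apart, 1.15 times the mean of 16134 over 1000 random placements at least 1 bp apart within the span, and above the highest, 16490. Gaps of 5 to 20 bp were in like excess, 1.17 times, whereas gaps of 3 to 4 bp were 0.877 times as frequent. The random placement took no account of footprints lying toward the middle of sites. The excess at 1 to 2 bp thus need not be particular to close pairs. No biological explanation was tested.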
